A study of Arabidopsis thaliana with 9 samples.

How the data were processed

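RNA was measured in 9 libraries of Arabidopsis thaliana pollen tubes, in 3 groups of 3. Per the labels, pollen came from a line in which the promoter of the sperm histone gene MGH3 (listed as HTR10 here) drives an MGH3-GFP fusion and the promoter of the actin gene ACT11 drives a red H2B fusion, and sperm cells and vegetative nuclei were isolated by fluorescence-activated sorting. Libraries were made with Smart-seq2, per the labels' protocols. Smart-seq2 amplifies full-length cDNA by PCR, adds no molecular identifiers and does not keep the strand.

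The deposited table holds raw counts per gene for each library, and per the submitters' processing notes the reads were trimmed with Trim Galore, aligned with HISAT2 to TAIR10 and counted with featureCounts. Tool versions, the strand setting, the gene set and the treatment of reads that map to several places are not given in the sources used here. Reads of a gene and its antisense partner therefore cannot be told apart, and values of close paralogs are uncertain. The table has 32833 genes by AGI locus code, every entry names a gene, and whole numbers summing to a different total in each library fit raw counts. Of these loci, 32548 (99.13%) were found in the reference gene table, which gave symbols and descriptions, and 27444 are protein-coding there. The reference is the TAIR10.1 assembly, while the counts were made on TAIR10, so no coordinates are printed. No counts in any library were found for 2874 loci.

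Sperm cells from semi in vivo tubes were compared with sperm cells from in vitro tubes, and in vitro sperm cells with in vitro vegetative nuclei. Each comparison used the counts of its own 6 libraries in edgeR 4.0.16 under R 4.3.3: filterByExpr on the groups compared (minimum count 10), TMM factors, a quasi-likelihood fit with robust dispersion, the F test and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Values per group are TMM-normalised CPM, counts scaled by library size, as mean ± SD with n = 3, scaled within each comparison, so the same in vitro sperm libraries have other CPM values in each. Standard errors of log2 fold changes were back-calculated as the absolute log2 fold change over the square root of the F statistic. For a gene with no counts in a group, the fold is a lower bound against 3 counts over that group. Such bounds cover counting error only, since PCR copies without molecular identifiers are not independent molecules. Nothing in the labels says that the replicates came from separate plants or growth assays, so p-values measure only the spread between these samples, which may be technical. No pair of libraries of 1 group was close to a duplicate: a chi-square of their counts was 28.03 to 401.7 per gene.

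Before the data were examined, the tests, 20 gene lists and the rule for named genes were fixed. The rule takes up to 12 higher and 12 lower genes with the largest log2 fold change among genes past the threshold, with no overlap between the groups and a mean of at least 10 CPM in the higher group. It adds up to 4 members of each list with the smallest adjusted p, and the 2 genes behind the sorting markers. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over lists with at least 5 tested members. The planned list of transposable element genes could not be tested because the reference has no such gene type, which leaves 19 lists. None of the 133 chloroplast-encoded genes passed the expression filter in either comparison. Members whose code carries another symbol in the reference, or whose symbol was not found, were left out: DAA1, SLR1, BUB1, HUP7, HUP9, HUP17, HSP70-4 and EXO84A. The rule for cytosolic ribosomal proteins was matched to gene descriptions 3 times, after the counts had been received and before any test result was seen. The last matching, with 138 loci, is used, and results with both earlier ones are given. The proteasome list, matched by description, also holds FUS6, a subunit of the COP9 signalosome.

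Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample weights, no expression filter, a filter of 5 CPM in 3 libraries, each library left out, a block on the replicate number, all 9 libraries in 1 fit, no organelle genes, counts thinned to the shallowest library, a minimum fold of 2, semi in vivo sperm in place of in vitro sperm, an estimated correlation in camera, and fry. Chosen after seeing the data were 1 library of each group left out in all 9 ways, TMM factors from genes with at least 10 counts in all 6 libraries or from genes before the expression filter, both between sperm and nuclei, and the earlier matchings of the ribosomal list.

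The procedure was tested on simulated counts with 200 changed genes. At each fold 40 genes were changed, and changed genes that failed the expression filter in the simulation are left out of the edgeR shares. With the means and spread of the sperm comparison (11240 genes past the filter), 27 to 36 of each 40 passed it. Of these, edgeR recovered 12.1% at 2-fold, 40% at 4-fold, 57.6% at 8-fold, 74.1% at 32-fold and 94.4% at 128-fold, with 8 false calls among 97. With the means and spread of sperm and nuclei (11874 genes past the filter), 33 to 36 of each 40 passed it. Of these, edgeR recovered 0%, 0%, 0%, 27.3% and 39.4%, with 1 false call among 23. The folds of 32 and 128 were added after the smaller ones gave none there. Far fewer genes changed in this simulation than the 6320 of 14061 called in the data. That makes the adjusted threshold stricter in the simulation, so its recovery does not carry over to the real comparison. DESeq2 made 70 false calls among 173 in the first simulation and 139 among 208 in the second. Simulated lists with no change were not called (0 of 19 in each, with the preset or the estimated correlation), and the changed list of 30 genes was called in both. Simulated genes varied independently of each other, so these lists cannot show false calls that come from correlated genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Mature pollen, which the design text mentions, is not analysed here.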

Results

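The study followed the transcripts of the Arabidopsis male germline while pollen tubes grew. Sperm cells were sorted from tubes grown for 6 h on germination medium (in vitro) and from tubes grown for 6 h semi in vivo. The semi in vivo tubes spent 2 h on an intact wild-type pistil and 4 h with the cut pistil on medium, where they emerged from the cut end. Vegetative nuclei, from the larger cell that forms the tube, were sorted from in vitro tubes. Each of the 3 groups has 3 libraries.

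Total counts were 14470065, 40525238 and 36692917 in the in vitro sperm libraries, 24005795, 41118337 and 32872736 in the semi in vivo sperm libraries and 13768069, 35157304 and 27331280 in the vegetative nucleus libraries. Few genes dominated the sperm libraries. DAF1 (AT3G62230) alone took 17.1% to 20.7% of their counts and the 10 most abundant genes 42.8% to 49.3%. In vegetative nuclei the 10 most abundant genes took 19.3% to 20.9%. In vitro sperm library 2 had 14203 genes at 1 CPM or more, against 7462 to 9867 in the other 5 sperm libraries, and vegetative nucleus library 1 had 6299, against 10086 and 8405 in the other nucleus libraries. The first principal component of log2 CPM held 67.8% of the variance and separated sperm from nuclei.

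**Figure D1:**
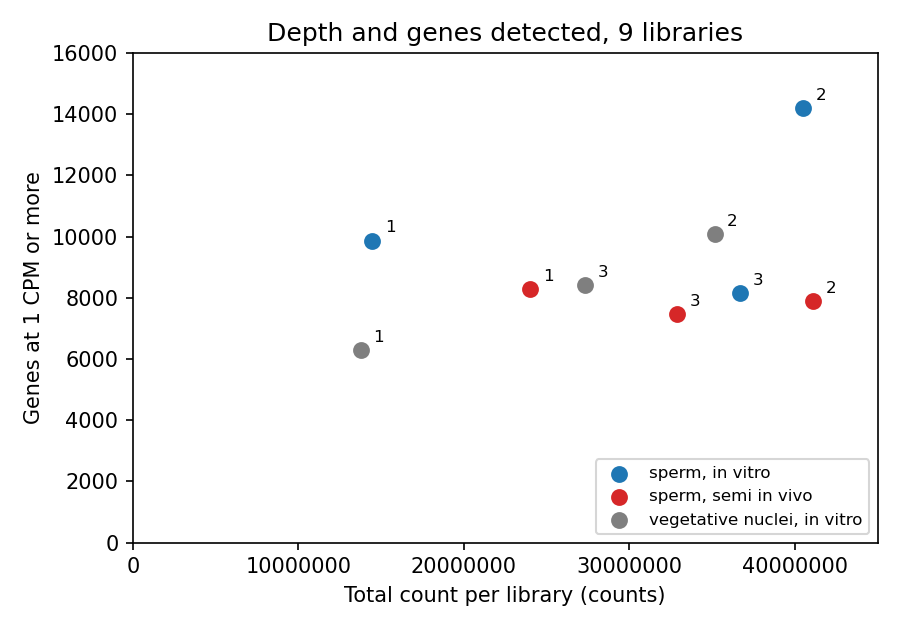
Genes at 1 CPM or more (y axis) against total count per library (x axis) for each of the 9 libraries, coloured by group and numbered by replicate. In vitro sperm library 2 lies highest, with 14203 genes from 40525238 counts, while semi in vivo sperm library 2 has 7897 genes from 41118337.

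The genes behind the sorting markers separated the sorted fractions. HTR10 (AT1G19890), the male-gamete histone H3 whose promoter drives the green marker, had 857.3 to 1540 CPM per sperm library before TMM scaling and 7.61 to 21.36 CPM per nucleus library. These counts may include the MGH3-GFP fusion, and the fractions were sorted on these markers, so the separation is no independent check. ACT11 (AT3G12110), whose promoter drives the red marker, had 733.8 to 1291 CPM in the nucleus libraries and 19.83 to 52.24 CPM in the sperm libraries.

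Sperm cells of tubes that had passed through pistil tissue were compared with sperm cells of tubes grown on medium. RALFL18 (AT2G33130), which encodes a secreted peptide of the rapid alkalinization factor family, rose 10.5-fold, from 2.15 ± 1.11 to 23.3 ± 1.76 CPM (SD, n = 3). AIR12 (AT3G07390), an auxin-responsive gene, rose 5.75-fold, from 17.8 ± 3.65 to 102 ± 17.7 CPM (SD, n = 3). The MADS-box gene AGL77 (AT5G38740), the embryo transcription factor gene LEC1 (AT1G21970) and the cell wall xyloglucan enzyme gene XTH11 (AT3G48580) also rose. GDPD2 (AT5G41080), of the phospholipase-C-like phosphodiesterases, fell from 18.3 ± 8.37 to 3.38 ± 0.723 CPM (SD, n = 3), and RAN-1 (AT5G20010), a small GTPase of nuclear transport, fell from 45.5 ± 20.7 to 12.2 ± 2.79 CPM (SD, n = 3).

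Of 14131 genes tested, 89 passed the threshold (edgeR quasi-likelihood, Benjamini-Hochberg), 76 higher and 13 lower in semi in vivo sperm, and 83 of them changed at least 2-fold. At an unadjusted p below 0.05 there were 1138 genes. The log2 fold changes were 3.40 for RALFL18 (SE 0.39, adjusted p = 0.000727), 2.83 for AGL77 (SE 0.53, adjusted p = 0.02), 2.52 for AIR12 (SE 0.23, adjusted p = 9.35e-05), 2.03 for LEC1 (SE 0.40, adjusted p = 0.0253) and 1.98 for XTH11 (SE 0.30, adjusted p = 0.00545), all by edgeR quasi-likelihood. LEC1 was low in both groups, at 13.9 ± 3.40 against 3.36 ± 1.43 CPM (SD, n = 3). The other genes among the 12 largest increases were the pectin lyase-like gene AT1G80140 (2.33), AT5G23470 (2.21), AT3G48230 (2.15), the WD40 repeat gene AT4G34380 (2.13), AT3G01295 (2.05) and the F-box genes AT2G07140 (2.03) and FOA1 (AT3G17320, 1.93). Among genes with at least 10 CPM in the higher group, 8 fell. These were GDPD2 (log2 fold change -2.43, SE 0.40, adjusted p = 0.00856, edgeR), AT1G48870 (-2.04), SRC2 (AT1G09070, -1.96), RAN-1 (-1.90, SE 0.31, adjusted p = 0.00859), the abscisic acid signalling kinase gene SNRK2.3 (AT5G66880, -1.30), ABCI19 (AT1G03905, -1.19), AT2G32360 (-1.17) and PICALM9c (AT2G01920, -1.01), of the ENTH family of clathrin adaptors. AGL77, AT4G34380 and the F-box genes belong to multigene families, and reads shared with close copies would make their values uncertain.

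**Figure D2:**
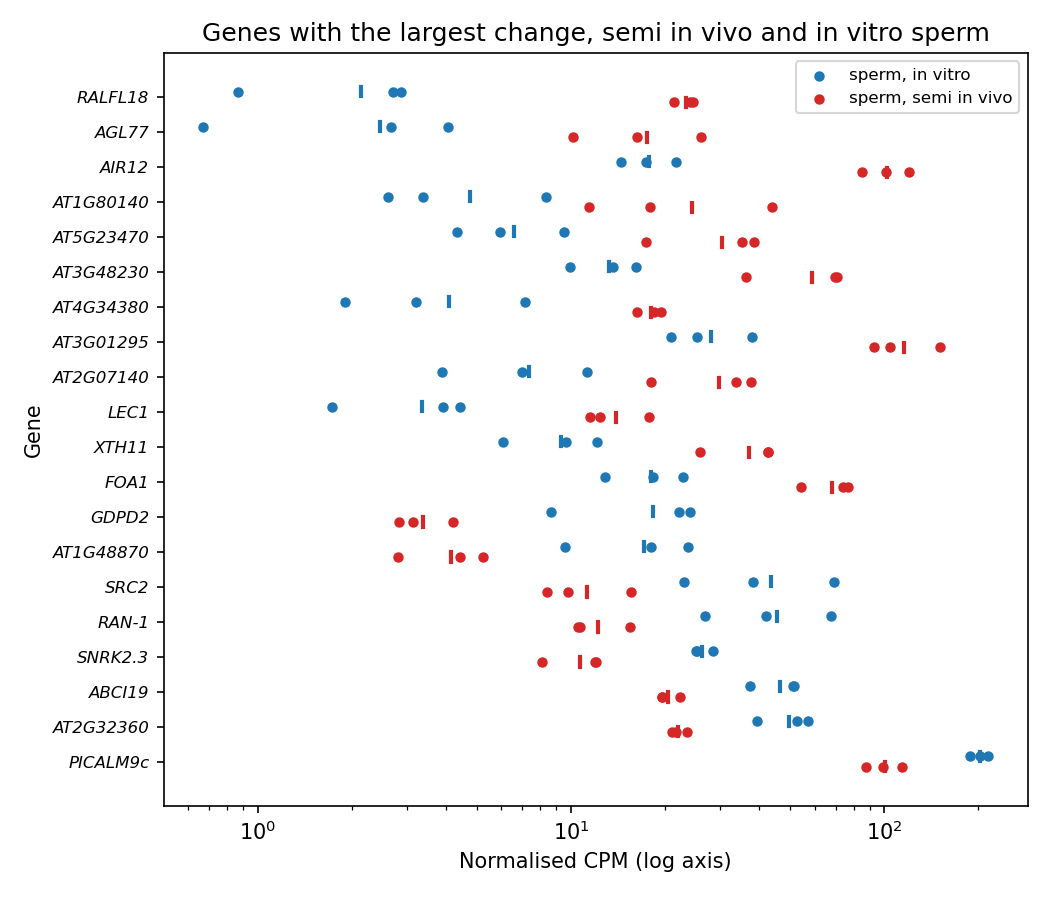
TMM-normalised CPM on a log axis for genes with the largest changes between in vitro and semi in vivo sperm, with a dot for each library and a bar for each group mean (n = 3). RALFL18 lies at 23.3 against 2.15 CPM and AIR12 at 102 against 17.8 CPM.

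The lists fixed beforehand held a single gene past the threshold over all genes, the sperm zinc finger gene DAZ3 (AT4G35700), which rose 1.70-fold from 9814 ± 1939 to 16710 ± 1735 CPM (SD, n = 3; edgeR adjusted p = 0.0457). Of 16 sperm markers tested, DAZ3 rose and 15 did not pass; adjusted over the list alone, 2 passed, DAZ3 and DAZ1 (AT2G17180, log2 fold change 0.84, adjusted p over all genes = 0.0995, edgeR). PCR11 (AT1G68610) had a log2 fold change of 0.32 (edgeR adjusted p = 0.615) and HTR10 of -0.34 (edgeR adjusted p = 0.695). The DAZ3 call was lost when in vitro sperm library 1 or 2 or semi in vivo sperm library 1 or 3 was left out, with an edgeR adjusted p of up to 0.231.

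Of 97 cytosolic ribosomal protein genes tested, 0 passed over all genes by edgeR and 0 adjusted over the list alone, and 64 had a positive log2 fold change. The list as a whole lay higher in semi in vivo sperm than the other genes (camera adjusted p = 0.00113), with a median log2 fold change of 0.21, or 0.37 above the median of all genes, and a mean of 0.11. The list had an adjusted p = 0.74 with an estimated correlation, 0.124 without semi in vivo sperm library 3, and 0.107 with the first matching of its rule (51 genes tested; 0.00248 with the second, 102 genes tested), all by camera. Semi in vivo sperm library 3 stood apart, with 11063 genes detected after thinning to 14470065 counts, against 16578 to 25741 in the other sperm libraries, and a second principal component of -181.7, against -4.41 and -4.57 in its group. In vitro sperm library 2 lay at the other end of that component, at 202.2, and had the most genes, 25741. emb2386 (AT1G02780), encoding a protein of the L19e family, had 90.9 ± 5.35 against 54.5 ± 2.67 CPM (SD, n = 3), and AT4G17390, of the L15e family, 69.4 ± 12.3 against 46.6 ± 6.14 CPM.

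No other list passed by camera. The wound, touch and jasmonate list had 7 genes tested, 0 past the threshold and a median log2 fold change of -1.49 (camera adjusted p = 0.0942). Its median CPM was 0.125 in semi in vivo and 0.966 in in vitro sperm, so its fold changes rest largely on low values. Adjusted over the list alone, JAZ10 (AT5G13220, 6.68 ± 1.11 against 1.64 ± 0.813 CPM, SD, n = 3) was higher and ZAT12 (AT5G59820, 97.8 ± 11.3 against 182 ± 68.9 CPM) lower. Of 15 tube guidance and integrity genes 0 passed (median -1.05, camera adjusted p = 0.0942), with COBL10 (AT3G20580) at 0.540 ± 0.602 against 3.05 ± 1.91 CPM. The median CPM of that list was also low, at 0.73 against 1.17. Of 24 DNA replication genes 0 passed (median 0.10, camera adjusted p = 0.0942), and of 20 mitotic genes 0 passed (median 0.02, camera adjusted p = 0.0942), while adjusted over the list alone 2 mitotic genes were higher, CYCA1;1 (AT1G44110, 92.9 ± 23.3 against 47.1 ± 9.91 CPM) and CYCB2;2 (AT4G35620, 28.5 ± 10.3 against 13.4 ± 0.933 CPM). None passed over all genes by edgeR among 18 vegetative cell markers (camera adjusted p = 0.53), 5 pistil markers (0.982), 27 DNA methylation and small RNA genes (0.147), 9 histone variant genes (0.567), 11 hypoxia genes (0.514), 11 heat genes (0.147), 12 endoplasmic reticulum folding genes (0.982), 22 exocytosis genes (0.789), 21 proteasome genes (0.147) and 8 mitochondrial genes (0.178). Before TMM scaling, all 16 pistil markers, tested or not, together had 30.1 CPM in in vitro sperm library 2 and 2.19 to 7.39 CPM in the other 5 sperm libraries. The 4 photosynthesis genes and 3 ovule genes tested were too few for camera. Adjusted over the list alone, RBCS3B (AT5G38410, 572 ± 45.9 against 344 ± 63.2 CPM, SD, n = 3), a small subunit of Rubisco, was higher and the mitochondrial ATMG01390 (11.6 ± 1.90 against 24.6 ± 4.26 CPM) lower; in the vegetative, pistil, methylation, histone, hypoxia, heat, endoplasmic reticulum, exocytosis, proteasome, tube guidance, replication and ovule lists 0 passed that way. The median and the test differed in sign for the pistil, heat and exocytosis lists, and the mean and the median for the methylation, heat and photosynthesis lists. Medians are read against that of all genes, which was -0.17 with TMM, -0.24 with RLE and -0.29 with upper-quartile factors.

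The number of genes called between the sperm groups was 51 without in vitro sperm library 1, 0 with all 9 libraries in 1 edgeR fit (996 at an unadjusted p below 0.05), 0 to 4 by edgeR with 1 library of each group left out (845 to 2641 at an unadjusted p below 0.05), 150 without an expression filter, 165 with the 5 CPM filter and 521 by DESeq2, of which 209 were higher and 312 lower. Of the 21 named genes called, 12 passed with any single library left out, among them RALFL18, AIR12, XTH11, GDPD2 and RAN-1, while AGL77, LEC1, AT1G80140, AT1G48870, SNRK2.3, ABCI19, AT2G32360, PICALM9c and DAZ3 did not in each of the 6 fits.

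Sperm cells were compared with vegetative nuclei from tubes grown in the same way. Genes of DNA replication took a larger share of the counts in sperm, where 21 of 24 tested rose, and genes of tube guidance and integrity a larger share in nuclei, where 22 of 23 were higher. CYCB1;3 (AT3G11520), a mitotic cyclin, had 119 ± 35 CPM in sperm (SD, n = 3) and no counts in nuclei, at least 4370-fold higher in sperm. AHA8 (AT3G42640), a plasma membrane proton pump of pollen, had 8774 ± 2758 CPM in nuclei and 1.72 ± 0.869 CPM in sperm, 5054-fold higher in nuclei. HTR10, whose counts may include the MGH3-GFP fusion, was 188-fold higher in sperm and ACT11 12.7-fold higher in nuclei. A whole cell, with its cytoplasm, was here compared with a nucleus.

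Of 14061 genes tested, 6320 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 4314 higher in sperm and 2006 higher in nuclei, all at least 2-fold. The split was 3399 and 2480 with TMM factors from unfiltered genes. The excess in sperm nearly disappeared with no expression filter (2433 higher in sperm and 2352 in nuclei). It was lost without nucleus library 1 and in vitro sperm library 2 (2307 and 2536) and without nucleus library 1 and in vitro sperm library 3 (1814 and 1870). At an unadjusted p below 0.05 there were 7285 genes. The median log2 fold change of all genes was 1.70 with TMM, 1.57 with RLE, 1.27 with upper-quartile factors, 1.01 with TMM factors from genes counted in all 6 libraries and 0.55 with TMM factors from unfiltered genes, so list medians are also given relative to it. Of the called genes, 1433 had no counts in nuclei and 97 none in sperm. The largest increases in sperm after CYCB1;3 were also at 0 in nuclei. They included MSI3 (AT4G35050), a WD40 protein gene, at least 3820-fold higher, IMPA-5 (AT5G49310), an importin alpha of nuclear import, at least 2700-fold, ERF10 (AT1G03800), a transcription factor gene, at least 2220-fold, and the phosphatase genes PPX2 (AT5G55260) and PP2C52 (AT4G03415), at least 2040-fold and 1940-fold. Bounds for the other 6, AT3G11960, CYP71B12, AT3G25480, AT4G04690, ATDAD1 and GLYR2, ran from 3670-fold to 1810-fold. In the other direction, AT2G23148, of the plant self-incompatibility protein S1 family, was at least 11000-fold higher in nuclei, the pectin lyase-like gene AT5G09280 at least 8420-fold and the thionin gene AT1G21925 at least 5860-fold, all at 0 in sperm. The peptide gene RALFL6 (AT1G60625) was at least 2700-fold higher in nuclei, the sucrose transporter gene SUC8 (AT2G14670) at least 1820-fold and the Rab GTPase gene RABA1f (AT5G60860) at least 1660-fold. AT3G44170, AT1G34800, AT1G34805 and AtBBE2 were also at 0 in sperm, with bounds from 2210-fold to 979-fold. CEL3 (AT1G71380), a cellulase gene, had 871 ± 119 CPM in nuclei and 0.0660 ± 0.0610 CPM in sperm. Several of these genes have close paralogs, so single values are uncertain.

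Of 16 sperm markers tested, 14 rose in sperm and 2 did not pass; adjusted over the list alone, 16 passed. The list median was 7.27 in log2, 5.57 above that of all genes (camera adjusted p = 0.000188; adjusted p = 0.328 with an estimated correlation). HTR10 had a log2 fold change of 7.55 (SE 0.60, adjusted p = 0.000567, edgeR), PCR11 of 6.97, DAZ3 of 7.10 and the tetraspanin gene TET12 (AT5G23030) of 6.09. All 27 vegetative cell markers were lower in sperm, over all genes and adjusted over the list alone (median -9.00, -10.71 relative to all genes, camera adjusted p = 5.7e-17; adjusted p = 0.257 with an estimated correlation). AHA8 had a log2 fold change of -12.30 (SE 0.79, adjusted p = 0.000555, edgeR), the cell wall gene LRX10 (AT2G15880) of -9.85, the pectin methylesterase genes VGDH1 (AT2G47030) and PPME1 (AT1G69940) of -9.75 and -10.82, and ACT11 of -3.67 (SE 0.48, adjusted p = 0.00173, edgeR). Of 23 tube guidance and integrity genes, 22 were lower in sperm over all genes and adjusted over the list alone (median -8.01, -9.71 relative to all genes, camera adjusted p = 4.27e-14; adjusted p = 0.257 with an estimated correlation). The cation exchanger gene CHX23 (AT1G05580) had 1958 ± 98.2 CPM in nuclei and 1.48 ± 0.898 CPM in sperm (SD, n = 3), COBL10 1009 ± 115 and 4.29 ± 1.89 CPM, and the receptor kinase gene BUPS2 (AT2G21480) 129 ± 24.7 and 1.51 ± 0.283 CPM.

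Genes of DNA replication were higher in sperm. Of 24 tested, 21 rose and 3 did not pass; adjusted over the list alone, 22 passed (median 6.91, 5.21 above that of all genes, camera adjusted p = 1.09e-05; adjusted p = 0.328 with an estimated correlation). ORC6 (AT1G26840), a subunit of the origin recognition complex, had 6073 ± 1383 CPM in sperm and 53.1 ± 18.9 CPM in nuclei (SD, n = 3). The replication licensing gene CDT1A (AT2G31270) had 991 ± 277 and 6.28 ± 0.896 CPM, and MCM7 (AT4G02060), a subunit of the replicative helicase, 814 ± 205 and 9.96 ± 3.14 CPM. Of 20 mitotic genes, 12 rose, 1 fell and 7 did not pass; adjusted over the list alone, 13 rose and 1 fell (median 5.13, 3.43 above that of all genes, camera adjusted p = 0.0285; adjusted p = 0.652 with an estimated correlation, and 0.103 without in vitro sperm library 3). CDKB1;2 (AT2G38620), a mitotic kinase gene, had a log2 fold change of 6.78, the Aurora kinase gene AUR3 (AT2G45490) of 6.90 and CYCB1;2 (AT5G06150) of 3.62, from 174 ± 32.8 CPM in nuclei to 2150 ± 572 CPM in sperm. Of 86 cytosolic ribosomal protein genes, 54 rose, 3 fell and 29 did not pass; adjusted over the list alone, 55 rose and 3 fell. Their median was 5.18, or 5.12 with genes at 0 placed at their bound, and 3.48 above that of all genes (camera adjusted p = 2.61e-05; adjusted p = 0.328 with an estimated correlation). AT2G17360, encoding a protein of the S4 family, had 213 ± 48.0 CPM in sperm and 7.67 ± 2.15 CPM in nuclei, and AT3G48960, of the L13e family, was at least 646-fold higher in sperm.

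Of 25 exocytosis and vesicle traffic genes, 4 rose and 7 fell, over all genes and adjusted over the list alone, and 14 did not pass. The list lay lower in sperm (median -1.64, -3.34 relative to all genes, camera adjusted p = 0.0115; adjusted p = 0.375 with an estimated correlation). The syntaxin gene SYP131 (AT3G03800) had 387 ± 27.3 CPM in nuclei and 0.771 ± 0.369 CPM in sperm (SD, n = 3), and the exocyst gene EXO70C2 (AT5G13990) 93.9 ± 26 and 3.52 ± 2.23 CPM. In contrast, the exocyst gene EXO70A2 (AT5G52340) rose to 260 ± 56.3 CPM in sperm from 34.4 ± 5.84 CPM in nuclei, and the vesicle protein gene VAMP725 (AT2G32670) to 87.2 ± 28.7 from 5.29 ± 2.67 CPM.

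**Figure D3:**
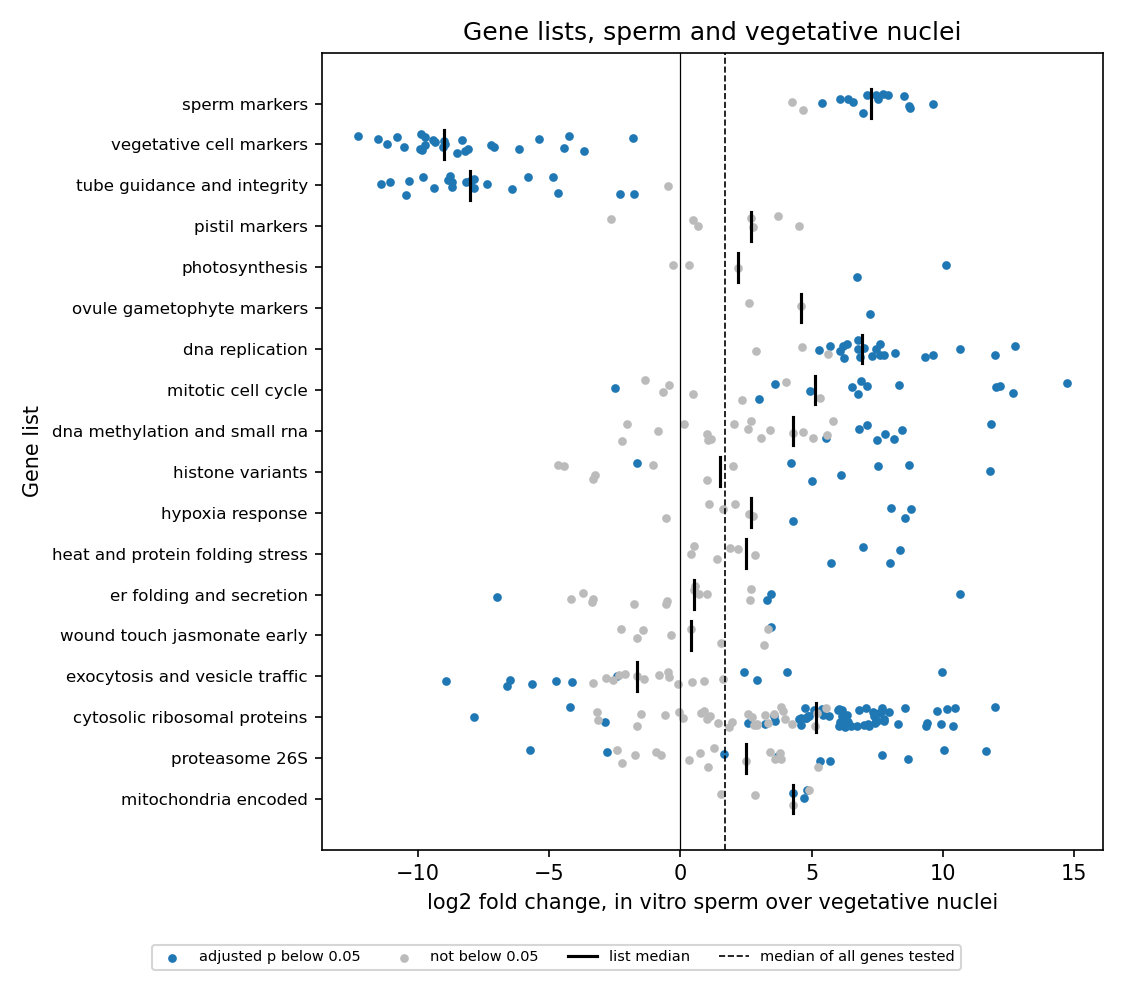
Fitted log2 fold change of in vitro sperm over vegetative nuclei (x axis) for the tested members of each gene list (y axis), blue where the edgeR adjusted p was below 0.05 and grey otherwise, with list medians as bars and the median of all genes, 1.70, as a dashed line. Fitted values of genes at 0 in a group depend on the prior count and are no bounds. Vegetative cell markers (median -9.00) lie left of 0 and sperm markers (median 7.27) right of it.

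The other lists did not pass by camera. Of all 14061 genes tested, 4314 rose in sperm and 2006 fell by edgeR, and the counts per list are read against those shares. Of 25 DNA methylation and small RNA genes, 8 rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0827). The maintenance methyltransferase gene MET1 (AT5G49160) had 644 ± 158 CPM in sperm and 4.66 ± 4.57 CPM in nuclei (SD, n = 3), the chromatin remodeller gene DDM1 (AT5G66750) 836 ± 210 and 17.9 ± 1.05 CPM, and the demethylase gene DML3 (AT4G34060) was at least 579-fold higher in sperm. Of 14 histone variant genes, 6 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.957); they include HTB8 (AT1G08170), with 433 ± 74.1 and 6.19 ± 7.10 CPM, and HTA6 (AT5G59870), at least 573-fold higher in sperm. Of 10 heat genes, 4 rose and 0 fell both ways (camera adjusted p = 0.37). The small heat shock genes HSP17.6A (AT5G12030) and HSP17.6C (AT1G53540) had 103 ± 130 and 95.6 ± 94.2 CPM in sperm and less than 1 CPM in nuclei, highest in in vitro sperm library 2, at 251.8 and 201.9 CPM. Of 10 hypoxia genes, 4 rose and 0 fell, and 3 rose adjusted over the list alone (camera adjusted p = 0.185). Among them LBD41 (AT3G02550) was at least 70.6-fold higher in sperm, from 1.93 ± 1.3 CPM. Of 25 proteasome genes, 8 rose and 2 fell, and adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 0.415), with RPT1A (AT1G53750) at 0.241 ± 0.319 CPM in sperm and 13.5 ± 3.27 CPM in nuclei and AT1G04810 at least 506-fold higher in sperm.

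Of 17 endoplasmic reticulum folding genes, 3 rose and 1 fell, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.292), with the co-chaperone gene ERDJ3A (AT3G08970) at 301 ± 51.9 CPM in sperm and 27.3 ± 14.6 CPM in nuclei (SD, n = 3). Of 9 wound, touch and jasmonate genes, ZAT12 rose, to 260 ± 70.3 CPM from 23.5 ± 24.8 CPM, and 8 did not pass, with 1 passing adjusted over the list alone (camera adjusted p = 0.771). Of 7 mitochondrial genes, 3 rose and 0 fell both ways (camera adjusted p = 0.0969), with ATMG00020 at 255 ± 74.9 and 12.9 ± 6.05 CPM. Of 5 photosynthesis genes, 2 rose and 0 fell both ways (camera adjusted p = 0.426), RBCS3B from 4.90 ± 3.66 to 526 ± 173 CPM and RBCS2B (AT5G38420) at least 176-fold. The RBCS genes are close paralogs and their values are uncertain. Of 7 pistil markers, 0 passed by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.899), with STK (AT4G09960) at 1.88 ± 1.45 and 0.137 ± 0.119 CPM. Before TMM scaling, all 16 markers of that list, tested or not, had 30.1 CPM in in vitro sperm library 2. In the others of that group they had 7.39 and 2.4 CPM. Of 3 ovule genes, too few for camera, EC1.5 (AT5G64720) was at least 23.8-fold higher in sperm, from 0.651 ± 0.268 CPM, and 2 did not pass; adjusted over the list alone 1 passed. For the pistil, endoplasmic reticulum and wound lists the median log2 fold change was above 0 and the test pointed lower, and the histone list had a median 0.18 below that of all genes with a test pointing higher. Relative to all genes, list medians had the same sign under all 5 scalings. Without that reference, the endoplasmic reticulum and wound medians changed sign, from 0.52 and 0.41 with TMM to -0.85 and -0.79 with TMM factors from unfiltered genes, where 2 endoplasmic reticulum genes rose and 4 fell.

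Fewer genes were called between sperm and nuclei without in vitro sperm library 1, 3552, and DESeq2 called 10578. Of the 82 named genes called, 72 passed with any single library left out. EC1.5 passed in 0 of the 4 such fits that tested it. Of 6 fits, SUS1 and PCO2 passed in 1, LBD41, WIP4 and BZIP28 in 2, and MBF1C in 3. HSP17.6II, ZAT12 and RPT1A passed in 5 of 6.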

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

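Leaving out 1 library of each group in all 9 ways, TMM factors from genes counted in all 6 libraries or from unfiltered genes and the earlier matchings of the ribosomal list were chosen after seeing the data. Between the sperm groups, the count of 89 genes became 521 with DESeq2, 150 with no expression filter, 165 with the 5 CPM filter and 0 with all 9 libraries in 1 edgeR fit (996 at an unadjusted p below 0.05; limma-voom on the 6 libraries called 112). It ran from 51, without in vitro sperm library 1, to 123 with 1 library left out. With 1 of each group left out, edgeR called 0 to 4, with 862 to 2641 genes at an unadjusted p below 0.05 where it called 0; other tools were not run on these. The count of 1 list became 6 with no filter and 0 to 5 with libraries left out: 2 without in vitro sperm library 1 or 2, 4 without library 3, and 3 and 0 without semi in vivo sperm libraries 1 and 3 (camera; 4 lists at an unadjusted p below 0.05 in the last). It was 0 with an estimated correlation (0 lists unadjusted), 0 with fry (1 unadjusted), 0 with the first ribosomal matching (5 unadjusted) and 0 with either earlier matching and an estimated correlation (0 unadjusted). Between sperm and nuclei, the count of 6320 genes became 10578 with DESeq2 and 1899 to 7138 with 1 or 2 libraries left out (3552 without in vitro sperm library 1). The count of 7 lists became 0 with an estimated correlation, with either earlier ribosomal matching too (camera; 2 lists at an unadjusted p below 0.05), and 14 with fry, which does not compare a list with other genes, and stayed at 6 to 8 with libraries left out. Fewer libraries leave fewer degrees of freedom, which by itself would not raise a count, and some counts rose. The cause of the changes was not tested. Apart from a block on the replicate number, every other alternative was within 1.5 times of these counts. No gene called in either comparison changed direction under any of these settings that tested it. However, all 89 and 6315 of the 6320 had no overlap between the groups, so leaving libraries out could hardly reverse them. The shallowest libraries, with 13768069 and 14470065 counts, limit detection, and thinning all to the shallowest gave 70 and 5940 genes.

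Same-numbered libraries did not deviate together in every pair (correlations -0.006, 0.064 and 0.17 between the sperm groups and 0.023, 0.066 and 0.004 between sperm and nuclei), and not every sample correlated best with its own number. With the replicate number as a block, 223 and 5790 genes and 1 and 8 lists were called.

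Over all alternatives, the log2 fold changes of named genes kept direction and side of the threshold in 1891 cases, fell short of it in 236, newly passed in 29 and changed sign in 37 between the sperm groups, and did so in 2369, 163, 21 and 16 cases between sperm and nuclei. The genes that changed sign, 11 and 4, did not pass in the settings that changed it, and the cause was not tested. Of these, GAPB alone passed in any setting, between sperm and nuclei without nucleus library 2 and in vitro sperm library 3 (edgeR adjusted p = 0.0401). NGA3 between the sperm groups was 0.10 with limma-voom and 0.019 with the block. Between sperm and nuclei, LHCA3 was -0.056 with upper-quartile factors, -0.77 with no filter, -0.772 with TMM factors from unfiltered genes and -0.26 with those from genes in all libraries, and JAZ10 was 0.27 with semi in vivo sperm. The other changes of sign came with libraries left out. Across all alternatives that tested them, values in the sperm comparison ran from -0.22 to 0.70 for ACT11, -1.75 to 0.10 for BIP2, -3.93 to 0.35 for COX1, -0.031 to 3.10 for HSP90.1, -1.83 to 0.64 for HTR1, -0.62 to 0.002 for IRE1A, -7.22 to 1.36 for MYB98, -2.61 to 0.58 for NAD4L, -1.55 to 1.05 for NGA3, -0.52 to 1.60 for RBCS1B and -0.71 to 0.23 for RBCS2B. In the comparison with nuclei they ran from -0.31 to 8.33 for GAPB, -1.58 to 4.78 for LHCA3 and -0.70 to 4.50 for LOX3.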

Other observations

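The tests of gene families, of depth, the amount of nucleus RNA and the separate pistil and photosynthesis lists in in vitro sperm library 2, of the share of genes called higher in sperm and of ACT11 carry-over were chosen after the result was seen. Gene families named by their descriptions were tested for enrichment among the genes that differed between sperm and nuclei (Fisher's exact test, one-sided, 370 tests with Benjamini-Hochberg adjustment, against 11938 tested genes with a family name, 14.6% of them higher in nuclei and 30.8% higher in sperm). Enriched among genes higher in nuclei were plant thionins, with 28 of 30 (adjusted p = 3.66e-19), RALF peptides, with 14 of 19 (adjusted p = 1e-06), self-incompatibility S1 proteins, with 17 of 27 (adjusted p = 1e-06), and arabinogalactan proteins, with 11 of 15 (adjusted p = 2.92e-05). So were protein kinases (61 of 224, adjusted p = 2.92e-05, with 47 others higher in sperm), pectin methylesterase inhibitors (23 of 54, adjusted p = 2.92e-05), cation/H+ exchangers (11 of 18, adjusted p = 0.000294), ENTH clathrin adaptors (8 of 12, adjusted p = 0.0021) and proteins described as calcium-dependent (10 of 19, adjusted p = 0.00367), while proline-rich, calcium-dependent lipid-binding and myosin-related families had adjusted p from 0.0157 to 0.0452. Under the 4 other scalings, 29 thionin genes and 14 RALF genes were higher in nuclei. Members of such families are often close paralogs, and shared reads would count 1 transcript more than once.

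Families frequent among genes higher in sperm were ribosomal proteins of all compartments (82 of 150, adjusted p = 1.8e-07), pentatricopeptide repeat proteins, which act on organelle RNA (57 of 111, adjusted p = 0.000226), and WD40 repeat proteins (43 of 86, adjusted p = 0.00471), by the same exact test. Under the 4 other scalings, 69 to 82 ribosomal, 52 to 56 pentatricopeptide and 31 to 43 WD40 genes were higher in sperm. Between the sperm groups no family was enriched by Fisher's exact test (lowest adjusted p = 1 over 396 tests), although 3 F-box genes with an associated interaction domain, of 62 tested, were among the genes higher in semi in vivo sperm (unadjusted p = 0.00265).

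The 6 libraries of each comparison can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 89 genes between the sperm groups and the highest other split 0, and 6320 between sperm and nuclei against 0, so 1 of the 10 splits in each gave a count as large. For gene lists, the real split called 1 between the sperm groups and the highest other split 4, and 8 of the 10 splits gave as many. Between sperm and nuclei it called 7 and the highest other split 8, and 3 of the 10 gave as many.

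In vitro sperm library 2 alone among the sperm libraries had 3981 genes at 1 CPM or more, with a median of 1.58 CPM and 0.736% of its counts, and 35% of these reached 1 CPM in a nucleus library, against 17.9% of genes under 1 CPM in all sperm libraries. Depth is excluded, since with all sperm libraries thinned to 14470065 counts it still had 1.37 times the genes of the next. Genes of at least 100 CPM in nuclei and under 10 CPM on average in the other 5 sperm libraries took 0.176% of its counts. In the others they took 0.0786% to 0.121%. That was the outcome written beforehand for nucleus RNA as the cause. However, the choice of genes limits their level in the other 5 libraries and not in library 2. A higher share in library 2 was thus favoured by the choice and decides nothing. An admixture of the size of this excess would supply 0.301% of the 3981 genes at 1 CPM or more. This share excludes nothing, since these genes were chosen as under 1 CPM in sperm libraries that also hold counts of genes abundant in nuclei. All but 35% of the 3981 genes stayed under 1 CPM in every nucleus library. That argues against nucleus RNA as the main source and not as a part. Pistil markers met what was written for pistil RNA after their total had been seen. They had 30.1 CPM, led by SHP1 at 5.28 CPM and NTT at 4.22 CPM, against 2.19 to 7.39 CPM in the other 5. Of the 11 markers under 1 CPM in those, 6 reached it here, against 3981 of all 19768 such genes (Fisher's exact test, one-sided, p = 0.012). The 19768 include the 2874 loci with no counts in any library, which lowers their share. The test therefore cannot single out pistil RNA, which stays open as a part. Its adjusted p was 0.176 over 19 lists. By the same exact test, 7 of 15 proteasome genes (p = 0.0187) and 3 of 4 DNA methylation and small RNA genes (p = 0.0277) did likewise. Moreover, 5 of the 16 markers reached 1 CPM in other sperm libraries, and the nucleus libraries had 5.85 to 19.03 CPM. The tubes of this library and of the nuclei grew without a pistil, and their contents were sorted by fluorescence. For green tissue, the share of photosynthesis and pistil genes together, 0.0435%, decides nothing. In the other sperm libraries, 97.7% of their CPM lay in genes of at least 10 CPM there. The 19 photosynthesis genes under that level had 11.1 CPM, above library 1 by less than the SD of the others. That margin was set after the values were seen, and green tissue as a part stays open. Of the 14 photosynthesis genes under 1 CPM in the other sperm libraries, 1 reached it here, against 3981 of all 19768 such genes. This argues against green tissue as the main source. Library complexity was not tested, nor, with no group for it in the design, a biological explanation.

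More genes were called higher in sperm than in nuclei, 68.3% of calls. The share fell with the median of all genes over the scalings, to 57.8% with TMM factors from unfiltered genes, so the scaling may account for part of the excess, and it was not excluded as a cause. Without in vitro sperm library 2 and nucleus library 1, which stand apart in genes detected, the share was 47.6%, so these libraries may contribute to the excess. It was also 49.2% without nucleus library 1 and in vitro sperm library 3, and 50.8% with no expression filter, so the pair is not the only choice that ends or nearly ends the excess. With nucleus library 1 alone left out the share was 55.1%, and with in vitro sperm library 2 alone left out 57.6%. It rose to 79.6% without nucleus library 2 and in vitro sperm library 3. That a whole cell holds more kinds of RNA than a nucleus stays open, since cell type and fraction cannot be separated in this design.

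ACT11, the gene behind the marker for nuclei, was counted in all 6 sperm libraries at 2.01% to 5.29% of its level in nuclei. Carry-over of vegetative nucleus RNA would bring the other vegetative markers in like proportion, but the ACT11 share was at least 40.6 times the median share of 21 others, which speaks against nuclear RNA as the whole source. LRX11 had a higher share than ACT11, 10.2% to 16.4%. Vegetative cytoplasm, which was not measured, and expression in sperm cells stay open, as do reads shared with other actin genes.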
